A study of Mus musculus with 2 samples.

How the data were processed

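Tumour-infiltrating cells of MC38 tumours were profiled in 2 droplet libraries with 10x 5′ chemistry, 1 from vehicle and 1 from LC427 treated mice, and groups were taken from the treatment label of each sample. Per the labels' protocols, tumours were digested, dead cells removed and CD45-positive cells selected on beads before capture. The authors deposited for each library an unfiltered matrix of UMI counts over 32285 genes, with its lists of barcodes and genes. The submitters' processing notes name Cell Ranger 3.0.1, Seurat 3 and the GRCm38 (mm10) genome, while per the file headers the matrices come from Cell Ranger 4, so the version behind the counts is uncertain. The authors also deposited a table per library with a mean count signal, scaled to 1 total per cluster, and a log2 fold change for each gene in each of their clusters, 13 for vehicle and 11 for LC427. Those tables give no cell for a cluster, and apart from the values given next no result of the report uses them. In the authors' deposited table the highest cluster mean of Gzmf was 23.6 in vehicle and 0.571 in LC427, over separate clusterings. In vehicle Gzmf and Gzmd were highest in the authors' cluster 7 and the NK gene Ncr1 in their cluster 5. In LC427 all of these genes were highest in the authors' cluster 3.

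Barcodes with at least 1000 UMIs, at least 400 genes and at most 10% of UMIs from mitochondrial genes were called cells, 5245 in vehicle, where 137 were removed for mitochondrial share, and 6328 in LC427, where 12 were. Scrublet, run per library in scanpy 1.11.5, called 0 doublets in both libraries at its automatic threshold and was taken not to have worked. The design had called doublets left out. In its place the highest-scoring barcodes were left out at 0.8% per 1000 cells, 220 in vehicle and 320 in LC427. This rate was chosen after the data were seen, and keeping all barcodes is what the design as written gives. Counts per 10000 were log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours gave a shared-neighbour graph that was clustered with Leiden (leidenalg 0.10.2, igraph 0.11.9) at resolution 1, both libraries together with no integration. Lrba, Ctla4 and members of the 18 outcome lists that are not markers were left out of the variable genes. T-like clusters were clustered again on their own.

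Cells thinned to 1000 UMIs lost none, as this is the minimum for a cell. The markers, gene lists, cell limits and the rule for named genes were fixed before the data were examined. The rule that turns markers into cluster names was not. It was written after cells per library and cluster had been seen, in 2 versions. In the first, a cluster stayed unnamed where its 10 leading genes against all other cells held more markers of another class than of its own, and a T sub-cluster with raised NK markers was named NK. In the second, used here, leading genes of the first-level clusters were taken against cells of other classes, T sub-clusters with NK markers were kept as unresolved T cells, those with myeloid markers as mixed, and the CD4 and Treg names were merged, because 1 sub-cluster carried both. The change moved the monocyte/macrophage-like class from 2811 vehicle and 2904 LC427 cells to 3423 and 4038. It also moved the share of CD8-like among T-like cells, and the first version is kept as an alternative for both. Cells per library had been seen at 3 resolutions before the rule was fixed, and 3 treatments of doublets were computed in all. Whether a cluster's leading genes differ between the libraries outside it was checked after the shares had been seen, and sizes were not read as a difference where at least 5 of 10 did, apart from T-like cells, where this is stated. The design named Treg cells, and the merged class stands in their place, with cells gated by Foxp3 UMIs beside it. A name needed 3 markers in at least 10% of a cluster's cells. The cluster left unnamed, led by Tm4sf1, Ankrd1 and Sox9, had the leucocyte gene Ptprc in 6.22% of its cells and was 3.58% of vehicle and 6.11% of LC427 cells.

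UMIs were summed per class and library and given as CPM of the class total. Exact Poisson intervals were used for CPM, exact conditional binomial intervals for ratios, exact Clopper-Pearson intervals for shares, and log-scale intervals for ratios of shares. All cover counting error only, and UMIs of 1 cell are not independent, so they are too narrow. A count of 0 stood at 3 counts, which makes its fold a bound. Lists were described in classes with at least 100 cells in both libraries over genes with at least 20 UMIs, by the median log2 ratio and its percentile among 10000 random lists of the same size matched on expression. Named genes had at least 50 CPM in 1 library, at least 20 UMIs, a level no lower than in empty droplets (barcodes of 10 to 100 UMIs) and a fold of at least 1.5. They were ranked by the 95% bound nearest to 1, up to 10 each way, in the 4 classes with most cells in their smaller library. Some genes that the rule names are not reported here. Markers, ribosomal, mitochondrial, segment, haemoglobin, sex-linked and model genes were left out. Gene coordinates came from GENCODE M21 on GRCm38, matched by Ensembl identifier.

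The intervals and fold rule were tested on simulated counts drawn from the means of CD8-like cells over 7823 genes, of which 200 were changed. There 96.3% of intervals held the true fold, and an interval excluding 1 recovered 34.3% of 1.5-fold, 78.8% of 2-fold and 92.5% of 4-fold changes. For monocyte/macrophage-like cells over 11557 genes the shares were 95.5% for coverage and 79.1%, 90.9% and 100% for recovery. Unchanged genes passed 1.5-fold by counting error alone in 12.6% and 4.10% of cases. Of simulated lists without a shift, 4.2% and 4.8% fell outside the central 95% of matched random lists in the same classes. The simulated genes varied independently and held no shift shared by a library. These rates therefore check the calculation only, and do not cover lists of genes that vary together, as genes do in the real libraries. Of the other settings, 17 were chosen before the data were examined and covered UMI minimum, cell calling, mitochondrial limit, doublets, clustering, gating, scaling, free RNA, gene minimum and thinning. A further 6 were added after the data were seen, covering naming, the doublet rate, denominators and the total without Gm42418 and AY036118, which overlap ribosomal RNA. Free RNA in mature regulatory DC-like cells was estimated at the 50% limit set on it, so its subtraction there carries little weight. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.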

Results

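Single-cell RNA was measured in immune cells of MC38 tumours, a mouse colon carcinoma line grown in C57BL/6 female mice that received vehicle or LC427, a compound known here only by its code name. The tumours were taken on day 14, and cells carrying CD45, the surface protein of blood cells, were selected on beads before droplet capture. The series title names LRBA, a protein of the BEACH family that holds CTLA4 back from lysosomal breakdown, as the target, and loss of CTLA4 protein as the outcome, so the comparison asks how the immune cells of treated and untreated tumours differ. Each group had 1 library, and the number of mice behind a library is not given in the sources used here. No test between groups is possible with 1 library each, so differences carry no replicate check, and every interval given below is a 95% interval that covers counting error only. The vehicle library held 33711726 UMIs and the LC427 library 28732435. After filtering and removal of probable doublets, 5025 vehicle cells and 6008 LC427 cells were compared. Before that removal the median was 3560 UMIs and 1353 genes a cell in vehicle, against 2424.5 UMIs and 1089 genes in LC427, a gap in depth that stands behind every share below.

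Lrba and Ctla4 transcripts were at similar levels in the 2 libraries over all cells. Lrba (ENSMUSG00000028080; GRCm38 chromosome 3, 86224680 to 86782692, plus strand) had 13.5 CPM in vehicle and 14.8 CPM in LC427, a ratio of LC427 to vehicle of 1.10 (0.94 to 1.28). These Lrba levels lie under the 14.4 CPM and 20.5 CPM of empty droplets. Ctla4 (ENSMUSG00000026011; GRCm38 chromosome 1, 60887000 to 60915832, plus strand), the inhibitory receptor that competes for CD80 and CD86, had 41.0 CPM and 41.4 CPM, a ratio of 1.01 (0.92 to 1.10). In CD4/Treg-like cells, where Ctla4 was highest, it had 985 CPM in vehicle and 1005 CPM in LC427, a ratio of 1.02 (0.79 to 1.32) over 69 and 65 cells. CD8-like cells had 307 CPM and 261 CPM of Ctla4, a ratio of 0.85 (0.722 to 0.997), and 44.8 CPM and 51.6 CPM of Lrba, a ratio of 1.15 (0.77 to 1.71). In thinned CD8-like cells 25.6% of vehicle and 17.6% of LC427 cells had a Ctla4 UMI, a ratio of 0.686 (0.518 to 0.909), and the Ctla4 ratio of the class was 0.706. After each cell was thinned to 1000 UMIs, 49.3% of vehicle and 53.8% of LC427 CD4/Treg-like cells had a Ctla4 UMI, against 0.175% and 0.471% of monocyte/macrophage-like cells, which should lack it. Median depths before thinning were 1807 and 1465 UMIs in the former and 3622 and 2282.5 in the latter. In NK-like cells Ctla4 had 108 CPM and 57.2 CPM, a ratio of 0.53 (0.31 to 0.87) from 169 and 18 UMIs, which was 0.887 with a T sub-cluster carrying NK receptor genes counted in. Thinned shares there were 9.02% and 2.60%. Mature regulatory DC-like cells had 32.2 CPM and 90.5 CPM, a ratio of 2.81 (1.57 to 5.20), which was 16.0 with each library clustered alone and 11.8 with doublets removed at 1.6% per 1000 cells. Some other T cell genes were more often seen there in LC427 too: without thinning, Foxp3 in 1.53% of vehicle and 4.49% of LC427 cells, Cd8a in 0% and 2.56%, and Pdcd1 in 0% and 7.05%. Gzmb was seen in 4.58% and 5.13%, and Ifng went the other way, in 2.29% and 0.641%. Monocyte/macrophage-like cells had 1.25 CPM and 3.51 CPM of Ctla4, a ratio of 2.82 (1.6 to 5.14). These levels lie under the 22.8 CPM and 31.2 CPM of empty droplets and are read as background. These values are of RNA, and CTLA4 protein was not analysed here. With each library clustered on its own, the Ctla4 ratio in CD4/Treg-like cells was 0.510.

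NK-like cells took a lower share of the LC427 library. They were 366 of 5025 vehicle cells, 7.28% (6.58 to 8.04), and 154 of 6008 LC427 cells, 2.56% (2.18 to 2.99), a ratio of 0.352. In all other cells the leading genes of this cluster, Klra8 and Ncr1 among them, had a median log2 ratio of -0.02, with 3 of 10 at least 1.5-fold apart between the libraries. Mature regulatory DC-like cells had 2.61% and 2.60%. Conventional DC-like cells, not split into subsets, were 2.99% (2.53 to 3.49) of vehicle and 4.94% (4.41 to 5.52) of LC427 cells. These sizes are given without a comparison, because 5 of the 10 leading genes of the cluster, which include Plet1 and Ccl17, were at least 1.5-fold apart between the libraries in all other cells too. The same holds for plasmacytoid DC-like cells, at 0.617% and 0.915%. The NK-like ratio was 0.568 when cells down to 500 UMIs were kept and 0.246 at a minimum of 2000, so its size varied with the UMI minimum, which weighs on the shallower LC427 library.

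CD8-like cells were 5.91% (5.27 to 6.60) of vehicle and 7.21% (6.57 to 7.89) of LC427 cells, a ratio of 1.22. The class joined a sub-cluster led by Cd8a and Cd8b1, with 173 vehicle and 274 LC427 cells, and one led by histone genes, with 124 and 159. Cd8a was seen in 68.9% and 70.3% of the cells of these sub-clusters. At a minimum of 2000 UMIs and under the order-of-magnitude rule for calling cells no T subset was separated and every T-like cell bore the CD8 name, so the ratios of 0.743 and 0.721 there are those of all T-like cells and say nothing of CD8-like cells. Of the 10 leading genes of the larger T cluster, 5 were also at least 1.5-fold apart in all other cells, and 1 within the cluster itself. Those other cells include the smaller T cluster, 2.95% of vehicle and 5.69% of LC427 cells. T cell genes can differ there through its size alone, so this check decides nothing for T-like cells. T-like cells as a whole were 11.6% of vehicle and 9.94% of LC427 cells, a ratio of 0.856 that turned above 1 under 5 of the other settings, reaching 1.19 at a minimum of 500 UMIs. CD8-like cells were 50.9% (46.8 to 55.1) of T-like cells in vehicle and 72.5% (68.8 to 76.1) in LC427. That contrast depended on where sub-clusters were placed. In 1 of them 217 vehicle and 99 LC427 barcodes, led by Pde2a, Cd7 and Klra7, carried T markers and NK receptor genes together. They were kept as unresolved T cells. Counted as NK cells instead, as the naming rule first had it, they left a ratio of CD8-like shares of 1.07 in place of 1.42. Gating cells by their own UMIs gave 1.02, and counting the 113 vehicle and 316 LC427 mixed T and myeloid barcodes among T cells gave 1.11. It was 1.06 with doublets kept, 1.08 with outcome genes kept and 1.29 both with at most 5% mitochondrial UMIs and at resolution 0.5.

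The CD8 to Treg ratio, a usual readout of treatment directed at CTLA4, could not be given a direction. Regulatory and other CD4 T cells fell into 1 sub-cluster, with Foxp3, the regulatory T cell factor, in 21.6% of its cells and Cd4 in 44.0%. The ratio of CD8-like to CD4/Treg-like cells was 4.30 (3.30 to 5.68) in vehicle and 6.66 (5.12 to 8.78) in LC427, that is 1.55 times as high in LC427 (1.07 to 2.24). With Treg cells gated by Foxp3 UMIs, the ratio was 8.10 (5.86 to 11.4) in vehicle, from 340 and 42 cells, and 6.98 (5.34 to 9.27) in LC427, from 433 and 62 cells, which is 0.863 times (0.569 to 1.31). The first-level T cluster led by Izumo1r, Tnfrsf4, Il2ra and Ctla4 was 2.95% of vehicle and 5.69% of LC427 cells, a ratio of 1.93 (1.6 to 2.34). Of it, 95 vehicle and 258 LC427 cells lay in the sub-cluster set aside as mixed T and myeloid. That sub-cluster had 42 cells with a Foxp3 UMI, 12 in vehicle and 30 in LC427, against 29 in the CD4/Treg-like class, 13 and 16.

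**Figure D1:**
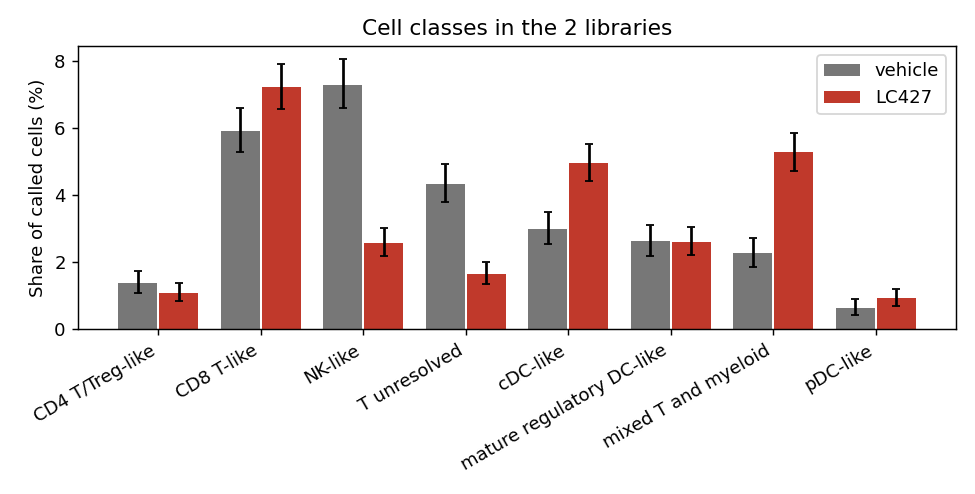
Share of called cells (%) in the vehicle and LC427 libraries, with exact binomial 95% intervals as bars. Shown are CD8-, CD4/Treg- and NK-like cells, conventional, mature regulatory and plasmacytoid DC-like cells, unresolved T cells and mixed T and myeloid barcodes. Monocyte/macrophage-, neutrophil- and fibroblast-like cells are not shown. NK-like cells are 7.28% in vehicle and 2.56% in LC427.

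Monocyte/macrophage-like cells were the most numerous class, and whether their total differed depended on the naming and on other settings. They were 68.1% (66.8 to 69.4) of vehicle and 67.2% (66.0 to 68.4) of LC427 cells, a ratio of 0.987, which was 0.738 with at most 5% mitochondrial UMIs and 0.711 with each library clustered alone. Cluster 0, led by Dpep2, Trem1 and F10, had 1 marker of another class and none of its own among its 10 leading genes against all other cells. With it left unnamed, as the rule was first written, the class was 55.9% of vehicle and 48.3% of LC427 cells, a ratio of 0.864. Taken by number, cluster 0 was 12.2% (11.3 to 13.1) of vehicle and 18.9% (17.9 to 19.9) of LC427 cells, but its ratio of 1.55 became 0.824 when cells were called by the order-of-magnitude rule. Cluster 5, led by Mmp13, Rsad2 and Mmp12, was 8.98% and 5.66%, a ratio of 0.631 that was 0.342 under the order-of-magnitude rule and 0.916 at resolution 2. Cluster 1, led by Pf4 and Lgmn, had a ratio of 0.916 (0.834 to 1.01), which was 0.619 at a minimum of 2000 UMIs and 1.10 with doublets kept, and cluster 8, led by histone genes, was 5.33% and 3.98%. Sizes of cluster 2, led by Cbr2 and Gas6, and of cluster 3, led by Ly6i and Fpr2, are not read as a difference between the groups, although their ratios were 0.495 and 1.85, because their leading genes differed between the libraries in the other clusters too, with median log2 ratios of -0.65 and 0.79. Cluster 2 held 26.6% of the class in vehicle and cluster 0 held 28.1% of it in LC427.

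Before single genes are read, 1 feature of the libraries bears on all of them. Log2 ratios of LC427 to vehicle moved together in unrelated classes: across 1491 genes, which are not independent replicates, Spearman's rho between CD8-like and monocyte/macrophage-like cells was 0.65, and the 10 pairs of classes lay between 0.60 and 0.78. The ratios rose with transcript length, with rho 0.20 in CD8-like and 0.34 in monocyte/macrophage-like cells. Folds below hold this shared part. Random lists were matched on expression and not on transcript length, so their ranges and percentiles do not take out the part linked to length. The median log2 ratio of all measured genes, against which list medians are to be read, was 0.13 in monocyte/macrophage-like and in NK-like cells and 0.06 in CD8-like and conventional DC-like cells.

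Within monocyte/macrophage-like cells, genes tied to tumour-associated macrophages were lower and interferon response genes higher in LC427. Of 15 measured tumour-associated macrophage genes, 9 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.74, below the central 95% of matched random lists (-0.15 to 0.27). Arg1, which breaks down arginine, had 2957 CPM in vehicle and 1776 CPM in LC427, a ratio of 0.601 (0.591 to 0.610). The mannose receptor gene Mrc1 had a ratio of 0.555 (0.534 to 0.577) and the scavenger receptor gene Cd163 0.256 (0.153 to 0.412), while Maf was at 1.00. The median was below 0 in each of the 6 clusters large enough to compare, from -0.83 to -0.30. Of 18 interferon gamma response genes, 6 were at least 1.5-fold higher and 0 lower, with a median of 0.46 at percentile 99.98. Guanylate-binding protein genes were among them, with ratios of 1.62 (1.54 to 1.69) for Gbp2 and 1.79 (1.59 to 2.01) for Gbp4, and Cxcl9, a chemokine that draws T cells, had 738 CPM and 1010.3 CPM. This list was not alike in all clusters, from -0.12 in cluster 5 to 0.55 in cluster 0, and with each library clustered alone its median was -0.06. It lay above its random range in clusters 0, 2 and 8 and inside it in clusters 1, 3 and 5. The type I interferon list had a median of 0.34 at percentile 99.6, which was 0.076 at a minimum of 2000 UMIs and -0.19 with each library clustered alone. By cluster it lay above its random range in clusters 0 and 5, inside it in clusters 1, 3 and 8, and below it in cluster 2, at -0.11.

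MHC class II genes of this class had a median log2 ratio of 0.33 at percentile 98.8, with 1 of 9 genes at least 1.5-fold higher, Ciita, their transactivator, at 1.78 (1.54 to 2.05). By cluster the class II median ran from -0.22 in cluster 5 and -0.09 in cluster 3 to 0.37 in cluster 2, which alone lay outside its random range. Inflammatory genes had a median of -0.41 at percentile 0.02, with 3 of 14 at least 1.5-fold lower, among them Cxcl1 at 0.443 (0.397 to 0.495) and Il1a at 0.578 (0.496 to 0.671). Costimulatory and coinhibitory ligands had a median of -0.16, below the random range of -0.13 to 0.39, which turned to 0.09 in thinned cells. By cluster it was below 0 in 5 of 6, from -0.85 in cluster 8 to -0.15 in cluster 1, below the random range in clusters 0, 1, 2 and 8, and 0.16 in cluster 5. Cd80 and Cd86, the ligands of CTLA4, had ratios of 1.11 (0.96 to 1.29) and 1.08 (1.00 to 1.18), and Pdcd1lg2, a ligand of PD-1, 0.312 (0.251 to 0.385). After thinning, 7.65% of vehicle and 8.69% of LC427 cells of the class had a Cd86 UMI, against 0.337% and 0.693% of CD8-like cells. Proliferation genes had a median of -0.16, below the random range of -0.02 to 0.28, which was above 0 under 3 of the other settings. By cluster it was above 0 in 5 of the 6, up to 0.52 in cluster 3, which alone lay above its random range. The other clusters lay inside theirs, and clusters 0, 1, 2 and 5 lay below the median of their random lists. The low value over the class was thus outside the random range in no single cluster, and cluster shares differ between the libraries.

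**Figure D2:**
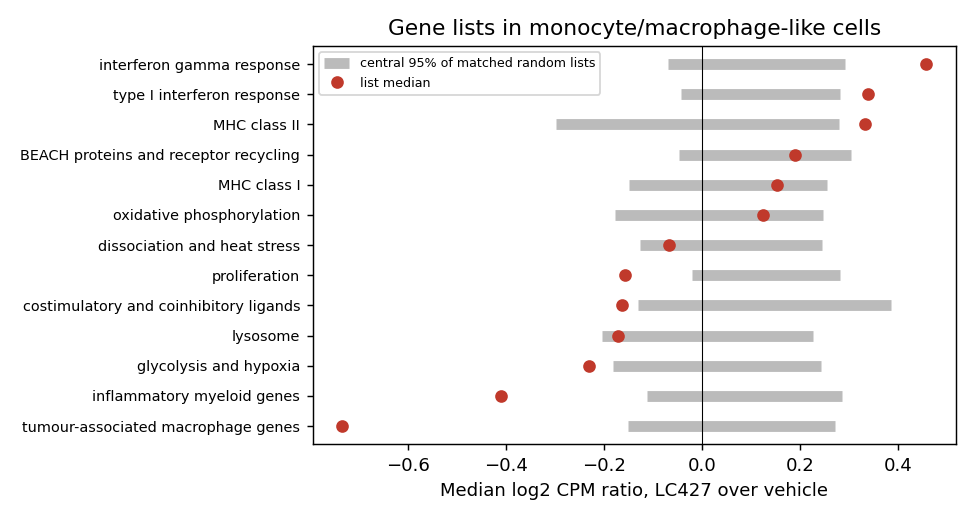
Median log2 CPM ratio of LC427 to vehicle for each gene list in monocyte/macrophage-like cells (points), with the central 95% of 10000 matched random lists as grey bars. The tumour-associated macrophage list lies lowest at -0.74 and the interferon gamma list highest at 0.46.

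Named by size alone, the genes most reduced in monocyte/macrophage-like cells of LC427 were the eotaxin gene Ccl24, from 113 to 11.3 CPM, and the chemokine gene Ccl8, from 2073 to 262 CPM, a ratio of 0.127 (0.122 to 0.131). The growth factor gene Hbegf had a ratio of 0.142 (0.114 to 0.175), and Timp1, a metalloproteinase inhibitor, 0.336 (0.298 to 0.378). Ccl24, Ccl8, Hbegf and Timp1 were lower in LC427 in all 6 clusters compared. Fabp5, a leading gene of cluster 5, at 0.368 and Ms4a4a at 0.405 were also lower in all 6, and Chil3 at 0.447 and Cxcl1 in 5 of 6. Cbr2 and Folr2, at 0.332 and 0.336, lead cluster 2 together with Ccl8, so the ratios over the class partly restate the clustering; within clusters they ran from 0.219 to 0.672 for Cbr2 and from 0.0798 to 0.373 for Ccl8. Higher in LC427 were Jaml at 3.74 (3.28 to 4.28), Spint1 at 3.38 (3.09 to 3.71), Dennd5b at 3.49, the interferon-inducible Ifi207 at 3.04 (2.85 to 3.24), Gpr141 at 3.02, Slfn1 at 2.72, Plac8 at 2.48, Rnf169 at 2.66, Dleu2 at 2.39 and Sla at 2.37, each higher in all 6 clusters. Jaml had 19.9 CPM in vehicle and 74.3 CPM in LC427, near the 20.9 and 73.2 CPM of empty droplets. Plac8 and Gpr141 lead cluster 3, and Plac8 turned to a log2 ratio of -1.03 with each library clustered alone. Of these 10 higher genes, 5 were higher in every other class in which they were measured. Of the 10 lower genes, 7 were measured elsewhere and 4 were lower in every other class measured. Hbegf was higher in LC427 in CD8-like cells, and Chil3 and Cxcl1 in conventional DC-like cells.

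In CD8-like cells, cytotoxic effector genes were lower in LC427. Of 17 measured, 5 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.48 at percentile 0.01. Gzmc, Gzmd and Gzme were among the 5. In vehicle Gzmd and Gzme stood at 70.6 and 55.4 CPM, under or near the 134 and 51.5 CPM of empty droplets. Gzmc stood over them, at 656 against 200 CPM. Ifng, the gene of interferon gamma, had 451 CPM and 316 CPM, a ratio of 0.701 (0.608 to 0.806), Gzmb 0.706 (0.633 to 0.788), and Prf1, which forms pores in target cells, 0.917 (0.786 to 1.07). After thinning, 26.3% of vehicle and 18.9% of LC427 cells had an Ifng UMI, against 0.0876% and 0.124% of monocyte/macrophage-like cells; without thinning the shares were 52.2% and 28.6%. Inhibitory receptor genes had a median of -0.08 at percentile 17.0, with Havcr2 at 1.56 (1.18 to 2.07) and Pdcd1 at 0.871 (0.703 to 1.08). Naive and memory genes stood at -0.30 and activation genes at -0.11, where Nr4a1, a target of receptor signalling, was at 0.471 (0.355 to 0.618). Dissociation and heat stress genes, a sign of handling, were also lower, with a median of -0.36 at percentile 0.13, as were glycolysis genes at -0.29.

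The named genes of CD8-like cells were mostly shared with other classes. Gapdh, the glycolytic enzyme, had 1288 CPM in vehicle and 469 CPM in LC427, a ratio of 0.364, and was at 0.485 in monocyte/macrophage-like and 0.282 in NK-like cells. Sh3bgrl3 at 0.349, Snrpd2 at 0.351, Pfn1 at 0.375, S100a11 at 0.378 and Lgals1 at 0.431 were lower in all 4 other classes too. Nr4a3 at 0.314 was lower in 3 of the 4, Gzme was at 0.190, and Slpi, at 0.191, was higher in LC427 under 4 of the other settings. Pdcd4 at 2.49, Bola2 at 2.21, Dhx15 at 2.24, Nol7 at 2.16, Eif3j1 at 2.29 and Snhg8 at 2.16 were higher in all 4 other classes, and Slc20a2 at 2.99 and Ddx10 at 2.33 in the 3 where measured. Itga4 at 2.35 was higher in 3 of 4 and Hspa9 at 2.08 in 2 of 4. In all, 8 of the 10 higher and 8 of the 10 lower genes kept their direction in every other class measured.

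In NK-like cells, a set of neighbouring granzyme genes on GRCm38 chromosome 14 was far lower in LC427. Gzmg had 10079 CPM in vehicle and 143 CPM in LC427, a ratio of 0.0142 (0.0104 to 0.0190). Gzme was at 0.0291, Gzmf at 0.0381 (0.0319 to 0.0451) and Gzmd at 0.0500 (0.0418 to 0.0594), while Gzmc, at 9281 and 4559 CPM, had a ratio of 0.491. The 5 genes took 4.18% of the UMIs of NK-like cells in vehicle and 0.563% in LC427. Empty droplets of the vehicle library had 143 CPM of Gzmg, far under the level in the cells. Over pooled UMIs, where deep cells weigh more, the middle of the 5 log2 ratios was that of Gzmf, -4.72. In cells thinned to 1000 UMIs the median log2 ratio of the 5 genes was -2.92, and with each cell weighing the same it was -2.99. The pooled ratios above are therefore more extreme than those with equal weight for each cell. In CD8-like cells Gzmc was at 0.429 (0.372 to 0.492), Gzmd at 0.567 (0.378 to 0.835), Gzme at 0.190 (0.0875 to 0.370) and Gzmf at 1.07 (0.932 to 1.22), while Gzmg had 6 and 2 UMIs. Gzmd and Gzme of vehicle CD8-like cells, at 70.6 and 55.4 CPM, lay under or near the 134 and 51.5 CPM of empty droplets. In LC427 they lay over them, at 40.0 and 10.5 CPM against 18.5 and 4.70. Among other cytotoxic genes, Gzmb had a ratio of 0.392 (0.330 to 0.462), below that of Gzmc. Gzma and Prf1 had ratios of 0.716 (0.658 to 0.778) and 0.661 (0.575 to 0.757), while Nkg7 was at 0.972 and Ctsw at 1.62. The cytotoxic list had a median of -0.60 at percentile 0.14, with 8 of 15 genes at least 1.5-fold lower and 3 higher. Also lower were Ctsg at 0.00870, Ifitm1 at 0.0887, Fcrl6 at 0.0664 and Tmsb15a at 0.123, and Tff1 and Dsc2, with 0 UMIs in LC427, were at least 8.54-fold and 6.34-fold lower against a floor of 3 counts over the class, with lower 95% limits of 6.85-fold and 5.06-fold. Proliferation genes had a median of 0.61 at percentile 99.85, 10 of 20 at least 1.5-fold higher, but thinned cells gave 0.16. Mki67, at 76.4 and 82.7 CPM, and Top2a, at 101 and 149 CPM, lay under empty droplets, at 182 and 177 and at 226 and 268 CPM. Hmgb2 in LC427 lay over them, at 725 against 559 CPM. After thinning, 5.74% of vehicle and 5.19% of LC427 cells had a Mki67 UMI, and 7.65% and 7.79% a Top2a UMI. The named higher genes, Slx1b at 6.66, Ccnb1ip1 at 4.34, Kif23 at 4.25, Wdr43 at 3.35, Pdcd4 at 3.05, Wdr89 at 2.93, Sart1 at 2.88, Noc2l at 2.83, Dhx15 at 2.49 and Nol7 at 2.22, were higher in every other class measured for 9 of the 10. Slx1b rests on 30 and 40 UMIs, Ccnb1ip1 on 23 and 20 and Kif23 on 20 and 17. In vehicle they had 19.1, 14.6 and 12.7 CPM, under the 32.8, 58.8 and 26.0 CPM of empty droplets. In LC427 they had 127, 63.6 and 54.0 CPM, against 120, 60.1 and 32.6 CPM. Of the 10 named lower genes, 6 were measured elsewhere and 3 were lower in every other class measured.

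**Figure D3:**
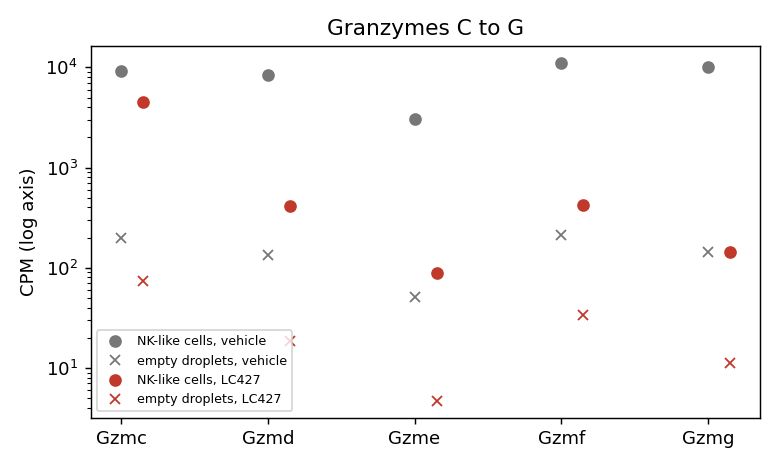
CPM (log axis) of granzymes C to G in NK-like cells (points) and in empty droplets (crosses) of the vehicle and LC427 libraries. Gzmg stands at 10079 CPM in vehicle and 143 CPM in LC427 NK-like cells.

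In conventional DC-like cells, interferon gamma response genes were higher in LC427, 12 of 17 by at least 1.5-fold and 0 lower, with a median log2 ratio of 0.91 above all 10000 matched lists. It was 0.49 with the doublet removal doubled. Gbp5, a guanylate-binding protein gene, had a ratio of 2.07 (1.37 to 3.20), and Cxcl10 0.891 (0.698 to 1.14). Proliferation genes were lower, 11 of 21 by at least 1.5-fold, with a median of -0.60. It was -0.15 with the doublet removal doubled, -0.35 in thinned cells and -2.24 with free RNA subtracted. Top2a was at 0.608 (0.478 to 0.773), but after thinning 7.33% of vehicle and 6.73% of LC427 cells had a Top2a UMI, a ratio of 0.918 (0.452 to 1.87). Inflammatory genes had a median of -0.44 at percentile 0.11, and MHC class II genes -0.03. The named genes higher in LC427 were Dennd5b at 5.87, Epb41l4aos at 3.16, Igtp at 3.01, Gpr141 at 2.96, Anapc4 at 2.84, Spint1 at 2.49, Dleu2 at 2.32, Ifi47 at 2.31, Ptpn12 at 2.23 and Tgfbi at 1.82. Lower were Ccl24 at 0.0513, Hfe at 0.280, Rsad2 at 0.328, Retnla at 0.339, Nr4a3 at 0.359, H2afx at 0.371, Trappc1 at 0.388, Ccl4 at 0.464, which was higher in LC427 with the doublet removal doubled, Gapdh at 0.471 and Pfn1 at 0.522. Of each set, 6 of 10 kept their direction in every other class measured. Retnla, Nr4a3, Rsad2 and Ccl4 were higher in LC427 in mature regulatory DC-like cells. Free RNA in conventional DC-like cells was estimated at 28.0% in vehicle and 39.4% in LC427. Ccl24 there stood at 58.2 and 2.99 CPM, from 47 and 3 UMIs, against 49.3 and 14.4 CPM in empty droplets. In mature regulatory DC-like cells, the interferon gamma list had a median of 0.44, with 6 of 15 at least 1.5-fold higher and 2 lower. It was 0.93 in thinned cells, 0.77 with the doublet removal doubled and 0.00 with free RNA subtracted, where the estimate stood at its limit. Dissociation and heat stress genes had a median of -0.53, which was -0.11 in thinned cells.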

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

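Tests of the shared shift across classes, and the granzyme tests by thinning and in empty droplets, were set down before their results were seen. The granzyme test on totals and the tests on mixed barcodes were chosen only after the result was seen. With 1 library per group no sample has others of its group to be set against.

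Abundant short transcripts such as Gapdh and Pfn1 were lower in LC427 in several classes. A library-wide difference in capture or RNA quality predicts that ratios move together in unrelated cells, and Spearman's rho between CD8-like and monocyte/macrophage-like cells was 0.65 across 1491 genes. A bias by transcript length predicts a positive relation in both, and the smaller rho was 0.20, barely past the value of 0.2 named in advance. Free RNA was left open, as the 33 genes lower in both classes had a median log2 ratio of -0.37 in empty droplets, between the bounds named in advance. A response of all classes to LC427 would also move them together, and it stays open as untested, since each group has 1 library.

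Granzymes C to G were lower in NK-like cells of LC427. With the 5 genes out of the totals their median log2 ratio was -4.77. They took 4.18% of the UMIs in vehicle, so leaving them out could change little and the outcome of this test was all but fixed. In cells thinned to 1000 UMIs the median log2 ratio was -2.92, so depth alone does not account for the lower values. Thinning gives each cell the same weight, and equal weight without thinning gave -2.99, so the smaller size is not evidence of a depth effect. In empty droplets the median was -2.85, which decides nothing, since fewer transcripts in the suspension lower the free RNA under either reading and the bound set for this test was wrong for that reason. An effect of LC427, a difference between tumours or animals and the placing of NK-like cells stay open, and no replicate tests them.

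Barcodes with both T and myeloid markers were 2.25% of vehicle and 5.26% of LC427 cells, a ratio of 2.34 (1.89 to 2.89). Pairs of cells in 1 barcode, if they form in proportion to the cells called and their class shares, predict a ratio of 1.02, or 1.31 with the mixed barcodes counted as T cells, both under the lower bound. Depth was not decided: the ratio was 2.78 at a minimum of 2000 UMIs, but these barcodes are deep, and removal of other cells alone would give 2.92. The prediction takes the cells called before doublet removal, while the ratio of 2.34 was counted after it. With doublets kept the ratio was 1.77, above both predicted values, but its interval was not set against them. The test therefore does not exclude pairs of cells. With more doublets removed the ratio was 5.23. Pairs of cells, depth, cells that stick together, a real interaction and uneven removal of doublets stay open.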

How the results depend on the processing

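Strict naming, the NK sub-cluster counted as NK, doublets at 1.6% per 1000 cells, both changed denominators and the total without Gm42418 and AY036118 were chosen after seeing the data, and the other settings before. Of the values under other settings for shares, lists, Lrba and Ctla4, 1849 stayed within the range set for the main value, 145 left it and 17 turned direction. For single named genes the numbers were 1222, 164 and 6. A turn was counted only where the main interval excluded no difference or, for lists, the main median lay outside its random range. Other values that crossed no difference, such as the CD4/Treg-like share from 0.788 to 1.28, are counted as inside or outside the range, so more values changed sign than these counts of turns. The lower NK share, the lower tumour-associated macrophage list and the lower Gzmd, Gzme, Gzmf and Gzmg in NK-like cells kept their direction under each setting that gave them a value. For values listed here the cause was not tested, apart from those that follow from another denominator or name. Depth limits the smaller classes, since a higher UMI minimum takes more cells from LC427. No paired analysis was possible because each group has 1 library. Values are ratios of LC427 to vehicle for shares, Lrba and Ctla4, and log2 ratios for lists and other genes.

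A minimum of 2000 UMIs, the order-of-magnitude rule and resolution 0.5 gave no value for CD4/Treg-like cells. Under that minimum and that rule no T subset was separated, so each value listed there for CD8 T, with the turned shares of 0.743 and 0.721, is that of all T-like cells. Sizes of clusters 2 and 3, 0.495 and 1.85 in the main analysis, and of fibroblast-like cells are listed as computed and not read as a difference. Unresolved T cells had none under that minimum, that rule, doublets kept, outcome genes kept, the NK sub-cluster counted as NK and each library clustered alone. Conventional and plasmacytoid DC-like cells had none with each library clustered alone, neutrophil-like cells none under 4 settings, and numbered clusters none where the Jaccard index with their best match was under 0.5. Resolution, outcome genes and gating bear on shares only, and scaling, free RNA and gene minimums on expression only. Free RNA subtraction in mature DC-like cells rests on an estimate at its limit of 50% and is not credible there.

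Under minimum of 500 UMIs, values were T 1.19, CD8 T 1.6, CD4 T/Treg 1.28, T unresolved 0.736, NK 0.568, myeloid 0.952, neutrophil 0.310. Others were among T cells, T unresolved 0.619, cluster 0 1.33, cluster 2 0.566, cluster 3 2.17, cluster 5 0.851, cluster 12 0.750, exhaustion in T -0.14. Further ones were type I IFN in T 0.20, proliferation in T -0.035, type I IFN in CD8 T 0.47, BEACH in NK 0.27. Under minimum of 2000 UMIs, values were T 0.743, CD8 T 0.743, NK 0.246, myeloid 0.864, among T cells, CD8 T 1.00, cluster 1 0.619, cluster 2 0.648. Others were cluster 3 1.37, thinned share Gzmb in CD8 T 1.19, thinned share Cd80 in mature DC 0.499, Ctla4 in T 0.734, exhaustion in T -0.16, IFN gamma in T -0.38, type I IFN in T -0.57. Further ones were stress in T -0.72, IFN gamma in CD8 T -0.38, type I IFN in CD8 T -0.57, stress in CD8 T -0.72, proliferation in cDC -0.26, glycolysis in mature DC 0.37, IFN gamma in myeloid 0.28. Also there stood type I IFN in myeloid 0.076, proliferation in myeloid 0.051. Under order-of-magnitude rule, values were T 0.721, CD8 T 0.721, NK 0.280, myeloid 0.909, among T cells, CD8 T 1.00, cluster 0 0.824, cluster 5 0.342. Others were thinned share Mki67 in CD8 T 0.487, thinned share Mki67 in NK 0.213, Lrba in T 0.876, Ctla4 in T 0.700, exhaustion in T -0.17, proliferation in T -0.11, Ctla4 in CD8 T 0.700. Further ones were lysosome in CD8 T -0.039, lysosome in NK -0.34, glycolysis in mature DC 0.34, lysosome in mature DC -0.15. With doublets kept, values were T 1.06, mixed 1.77, among T cells, CD8 T 1.06, cluster 0 1.28, cluster 1 1.10, cluster 2 0.389, cluster 5 0.540. Others were lysosome in mature DC -0.14. Under outcome genes kept, values were T 1.12, among T cells, CD8 T 1.08, cluster 5 0.539, cluster 12 0.627. Under natural killer sub-cluster as NK, values were T 1.14, among T cells, CD8 T 1.07, Ctla4 in NK 0.887. With Treg gated by Foxp3 UMIs, set against the merged CD4/Treg class, and other T cells gated too, values were T 1.05, CD4 T/Treg 1.24, among T cells, CD8 T 1.02, CD8 to CD4/Treg 0.863. Under each library clustered alone, values were CD4 T/Treg 1.65, myeloid 0.711, fibroblast 10.2, mixed 3.69, unnamed 2.48, among T cells, CD4 T/Treg 1.95, CD8 to CD4/Treg 0.703. Others were thinned share Mki67 in myeloid 1.12, thinned share Ctla4 in CD4 T/Treg 0.704, thinned share Cd86 in myeloid 0.913, Slpi in CD8 T 2.48, Ctla4 in CD4 T/Treg 0.510, Ctla4 in mature DC 16.0, IFN gamma in myeloid -0.058. Further ones were type I IFN in myeloid -0.19, proliferation in myeloid 0.085, Plac8 in myeloid -1.03. Under mt at most 5%, values were T unresolved 0.492, myeloid 0.738, among T cells, CD8 T 1.29, among T cells, T unresolved 0.552, cluster 0 1.35, cluster 5 0.454, Slpi in CD8 T 3.68. Others were type I IFN in cDC 0.31, proliferation in cDC -0.25, BEACH in cDC 0.14, type I IFN in mature DC 0.11, type I IFN in myeloid 0.12, proliferation in myeloid 0.065. Under resolution 0.5, values were T unresolved 0.515, among T cells, CD8 T 1.29, among T cells, T unresolved 0.606. Under resolution 2, values were myeloid 0.924, cluster 2 0.326, cluster 5 0.916. Under strict naming, values were myeloid 0.864. Under unnamed and mixed out of the denominator, values were myeloid 1.05. With doublets removed at 1.6% per 1000 cells, values were mixed 5.23, cluster 0 1.21, cluster 3 2.27, Slpi in CD8 T 2.49, IFN gamma in cDC 0.49, proliferation in cDC -0.15, Ccl4 in cDC 0.35. Others were Ctla4 in mature DC 11.8, IFN gamma in mature DC 0.77, Ctla4 in myeloid 5.27. Under mixed counted among T, values were among T cells, CD8 T 1.11, among T cells, T unresolved 0.348. Under mt at most 20%, values were cluster 0 1.36, cluster 1 1.05, cluster 2 0.428, cluster 12 0.683, Slpi in CD8 T 3.73, type I IFN in mature DC 0.038. Under thinned to 1000 UMIs, values were type I IFN in T -0.58, proliferation in T 0.50, Ctla4 in CD8 T 0.706, Ctla4 in NK 0.272, MHC class I in NK -0.53, proliferation in NK 0.16, BEACH in NK -0.66. Others were stress in NK -0.23, IFN gamma in cDC 0.60, proliferation in cDC -0.35, BEACH in cDC 0.15, ligands in mature DC 0.29, MHC class II in mature DC 0.30, IFN gamma in mature DC 0.93. Further ones were type I IFN in mature DC 1.25, lysosome in mature DC -0.25, stress in mature DC -0.11, Lrba in myeloid 1.70, ligands in myeloid 0.095. Under minimum of 10 UMIs a gene, values were type I IFN in T 0.31. Under mean over cells, values were proliferation in T 0.51, IFN gamma in NK -0.17, stress in NK -0.037, MHC class II in mature DC 0.27, inflammatory in mature DC -0.11. Under free RNA subtracted, values were lysosome in NK 0.00, proliferation in cDC -2.24, glycolysis in cDC -0.59, IFN gamma in mature DC 0.00, Ctla4 in myeloid 7.67. Under minimum of 100 UMIs a gene, values were lysosome in NK -0.058, ligands in mature DC 0.17, type I IFN in mature DC 0.070, stress in mature DC -0.084.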

Other observations

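Icosl, the ligand of the costimulatory receptor ICOS, stood out among the ligands because it was higher in LC427 in conventional DC-like cells, at 9.91 and 41.8 CPM with a ratio of 4.22 (1.96 to 10.4), and in monocyte/macrophage-like cells, at 5.83 and 9.76 CPM with a ratio of 1.67 (1.26 to 2.23). In mature regulatory DC-like cells it was at 37.6 and 38.5 CPM. It was singled out after its values were seen.

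The BEACH and receptor recycling list, fixed for the family of LRBA, had median log2 ratios of 0.12 in T-like, 0.00 in CD8-like, -0.12 in NK-like, -0.17 in conventional DC-like, 0.23 in mature regulatory DC-like and 0.19 in monocyte/macrophage-like cells, each inside the central 95% of matched random lists. Within monocyte/macrophage-like cluster 8 it was 0.47, above its random range of -0.14 to 0.35, with 6 of 17 genes at least 1.5-fold higher and 1 lower. Cluster 8 was picked out of 6 after the values were seen, and in the other 5 the list lay inside its random range, from 0.024 in cluster 2 to 0.31 in cluster 1.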
